A study of Rattus norvegicus with 18 samples.

How the data were processed

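RNA-seq was analysed in 18 libraries of rat brain, 6 in each of 3 groups. Groups and library numbers came from the sample titles. Per the labels' protocols, RNA was isolated with a column kit, 1.3 µg of total RNA went into each library, and libraries were made with a SMARTER mRNA-Seq kit. Strandedness is not stated, so reads of overlapping or antisense genes cannot be told apart.

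The authors deposited 1 table of raw, whole-number counts per gene for all 18 libraries, with no normalization. It lists 34873 genes, of which 32545 carry rat Ensembl gene IDs. The other 2328 are unnamed loci, which took 1.21% to 1.62% of the counts of a library. They were kept in library sizes and tests but could not be named. The aligner, the counter and the genome build are not given in the sources used here. The labels name only the mouse builds GRCm38 and mm10, per the submitters' processing notes, although gene IDs, symbols and coordinates in the table are of rat. Coordinates are therefore printed as the table gives them, with no build. Symbols came from the table. The depth per library was 15.1 to 20.3 M counts, and the 10 highest genes took 10.1% to 16.8% of them. Protein-coding genes of the mitochondrial genome took 8.86% to 14.9% of the counts, with means of 12.2% in NC, 10.0% in CO and 11.5% in CLCF1. Ribosomal RNA took 0.489% to 1.80%.

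Counts were tested with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were removed by filterByExpr with its defaults (18292 of 34873 genes), and all 18 libraries entered 1 quasi-likelihood fit with robust estimation. The common dispersion was 0.0972, a biological coefficient of variation of 0.312. The contrasts were CO against NC, CLCF1 against CO and CLCF1 against NC, each with Benjamini-Hochberg adjustment over the 16581 genes tested and a threshold of 0.05. The standard error of a log2 fold change was derived from the fold change and its F statistic. A fold change against a group with no count was computed as a bound, with 3 counts over the group in place of 0, and with 1 to 3 counts as a ratio of counts with a 95% exact binomial interval. These intervals cover counting error only, since the labels name no molecular identifiers. For Clcf1, mean log2 CPM (prior count 2) was also compared with a two-sided exact permutation test over 924 splits.

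Gene lists were tested as groups with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, against all other genes tested and with adjustment over lists. Camera with an estimated correlation and the directional test fry were run beside it. The 45 lists cover pathways named by the series title or by CO exposure, stress responses, cell types and brain regions. They held 835 symbols, of which 781 were found, and the 42 lists with 5 or more genes tested were used. Genes named in the text followed 1 rule with 3 parts. The parts were Clcf1 and its receptor genes, and the 10 genes with the largest rise and the 10 with the largest fall among those passing, with a symbol, a mean log2 CPM above 0 and the same sign when any 1 library was left out. The last part was up to 4 genes with the smallest p of each list that passed or held a passing gene. Genes named outside this rule are said to be so, and some that it selects are not reported here. The groups, the tests, the lists, this rule and all alternatives but 2 were chosen before the data were examined. The exceptions are fits on libraries 1 and 2 alone and on libraries 3 to 6 alone, which were chosen after the data were seen.

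The other alternatives were the library number as a block, DESeq2 size factors or library size alone as scaling, no filter or a stricter one (10 counts in 6 libraries and a mean CPM of 1), DESeq2 1.42.0, limma-voom with sample quality weights, fits of only the 2 groups compared, an absolute log2 fold change of 1 or more, and leaving out each library in turn. The 2 contrasts that share the CO libraries were compared with 100 simulated draws without any change and with the CO libraries divided between them in 20 ways. Replicate pairs were compared by chi-square on genes with a count of 20 or more. Chi-square per degree of freedom ran from 39.1 to 70.8, so no pair differed by as little as sampling noise. Co-variation of lists used 10944 protein-coding genes with a mean count above 100, and 200 random lists served as background. Its statistic is the variance of the mean log2 CPM of a list divided by that of independently varying genes, and on simulated independent genes its median was 0.994 among libraries 3 to 6, against 5.33 with a shared factor per list.

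The tests were checked on simulated counts with known changes. The genes whose recovery is given had an expected count above 100, so recovery at lower counts was not simulated. Simulated libraries were independent of each other, which libraries 3 to 6 may not be. For CO against NC (16370 genes), 34.8% of genes with an absolute log2 fold change of 0.58 were recovered, 80.6% of those with 1 and 97.0% of those with 2, and 6 of 148 calls were false. For CLCF1 against CO (16353 genes) the shares were 31.8%, 74.6% and 95.5%, with 4 of 140 calls false, and for CLCF1 against NC (16357 genes) 22.7%, 76.1% and 97.0%, with 9 of 142. Most simulated changes of the smallest size were thus missed, and a gene that did not pass is not shown to be unchanged. Values per library were screened with Dixon's ratio, for genes on log2(CPM + 0.1). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3. Nothing in the table was left out except genes removed by the filter.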

Results

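RNA-seq counts from rat brain were compared between 3 groups of 6 libraries each. The NC group was wild-type and untreated, and the CO group was wild-type and had inhaled carbon monoxide (CO). The CLCF1 group had also inhaled CO and is labelled as a knock-down of Clcf1, the gene of cardiotrophin-like cytokine factor 1, a secreted ligand of the ciliary neurotrophic factor receptor. Per the design text, rats breathed 1000 ppm CO for 40 min and then 3000 ppm for 20 min, and carboxyhemoglobin exceeded 60%. It also describes lentiviral knock-down or overexpression of Clcf1 in bone marrow-derived macrophages, and the transfer of such macrophages to rats whose own had been depleted with liposomes. It does not state whether NC and CO rats were also depleted and given macrophages, so the CLCF1 and CO groups may differ in more than the knock-down. The series title names the question: whether CLCF1 and NF-κB act on the clearance of dying cells by macrophages (efferocytosis) and on neurological damage after CO poisoning. Total counts per library ran from 15.1 to 20.3 M (mean 17.5 M ± 1.47, SD), and 16581 of 34873 listed genes had enough counts to be tested. Below, ± after CPM, the count of a gene scaled to a common library size, is the SD of the 6 libraries of a group and ± after a log2 fold change is its standard error. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera. The labels do not say that the 6 libraries of a group came from 6 animals, so p-values measure only the spread between these libraries, which may be technical.

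Libraries 3 to 6 of each group differed from libraries 1 and 2 in how genes varied. In the 3 groups together, 42660 times a gene had no count in both library 1 and library 2 of a group, and in 0 of these cases did any of libraries 3 to 6 of that group hold a count. In libraries 1 and 2 of the other groups, 5.22% of such genes had counts on average, with a range of 2.90% to 8.92%. Over 39 gene lists, the variance of a list's mean between libraries 1 and 2 was a median 2.32 times that of genes varying independently, and among libraries 3 to 6 it was 0.836 times. Random lists gave 0.864 and 0.96, and 19 of the 39 lists lay above the 95th percentile of random lists between libraries 1 and 2, against 4 among libraries 3 to 6. Camera's estimated correlation drew on all 18 libraries, so the low co-variation of libraries 3 to 6 may lower it. List calls that held with an estimated correlation may therefore be too lenient. Values of libraries 1 and 2 alone, an alternative chosen after the data were seen, are therefore given for many of the genes and lists below. Genes called in all libraries were selected partly on libraries 1 and 2, so their values there are not independent of the call. P-values and counts of calls over all 6 libraries of a group, permutation p-values included, take these as independent samples. For libraries 3 to 6 the 0 of 42660 cases argue against that. In the other direction, at least 1.24% of genes at 0 in a pair of libraries 3 to 6 had counts in library 1 or 2. With libraries 1 and 2 alone, both libraries of one group lay above or below both of the other for 33.3% of genes by chance, and for 34.1%, 30.7% and 27.3% of all genes in the comparisons of CO with NC, CLCF1 with CO and CLCF1 with NC.

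**Figure D1:**
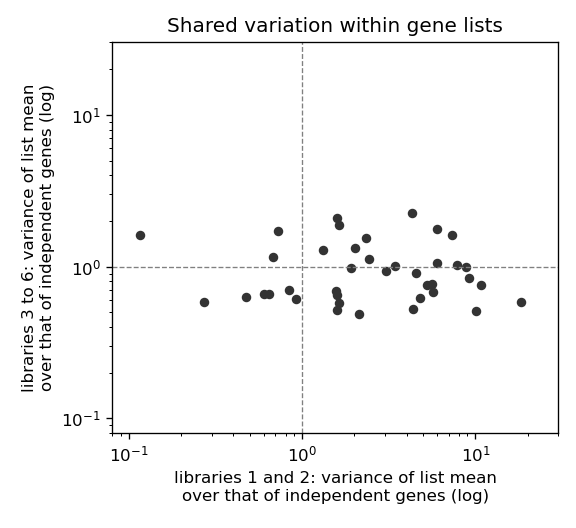
Each point is 1 of 39 gene lists with 5 or more abundant genes, placed by the variance of its mean log2 CPM relative to that of independently varying genes (log axes), between libraries 1 and 2 (x axis) and among libraries 3 to 6 (y axis) of the same group. The median was 2.32 on the x axis and 0.836 on the y axis, and dashed lines mark 1.

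Clcf1, the gene named in the knock-down label (chromosome 1, positions 219468675 to 219472654 as the count table gives them, in a genome build it does not name), had 2, 7, 3, 1, 3 and 2 counts in the NC libraries. The CO libraries held 88, 99, 80, 118, 117 and 92 counts, and the CLCF1 libraries 2, 1, 0, 0, 0 and 3. Its level rose from 0.161 ± 0.0905 CPM in NC to 6.23 ± 1.04 in CO (log2 fold change 5.19 ± 0.45, edgeR adjusted p = 7.46e-06, exact permutation p = 0.00216, two-sided). In the CLCF1 group it was 0.0549 ± 0.0701 CPM, lower than in CO in 6 of 6 libraries (log2 fold change -6.67 ± 0.51, edgeR adjusted p = 9e-07, exact permutation p = 0.00216, the smallest that 924 splits allow). The difference of -1.49 ± 0.60 between CLCF1 and NC did not pass (edgeR adjusted p = 0.126; exact permutation p of this gene alone = 0.0325). Libraries 1 and 2 alone gave log2 fold changes of 4.58, -6.05 and -1.47, none of which passed there. The receptor parts Cntfr, Lifr and Il6st passed in none of the 3 comparisons. Il6st, the shared signal-transducing chain gp130, came nearest, with 0.89 ± 0.31 in CLCF1 against CO (edgeR adjusted p = 0.0511). Of 15 ligand, receptor and JAK/STAT genes tested, 12 did not pass between CO and NC (camera adjusted p = 0.347). Besides Clcf1, Socs3, a feedback inhibitor of JAK kinases, rose in CO by 1.30 ± 0.40 and Tyk2, a JAK kinase, fell by 0.80. The Socs3 call was lost (edgeR adjusted p 0.0511 to 0.0771) without any 1 of NC libraries 1, 2, 4, 5 or 6 or CO libraries 1, 2, 4 or 6.

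**Figure D2:**
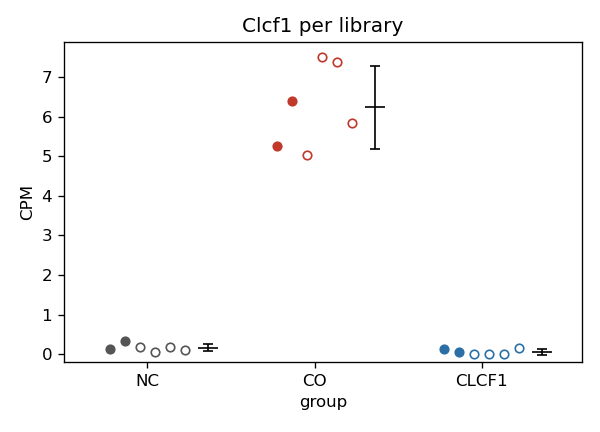
Clcf1 level in each of the 18 libraries in CPM, with filled points for libraries 1 and 2, open points for libraries 3 to 6, and bars for the mean and SD of the 6 libraries of each group. The CO group averaged 6.23 CPM, against 0.161 in NC and 0.0549 in CLCF1.

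The first comparison, CO against NC, asks what inhaled CO changed in brain. After CO, brain held more RNA of the chemokine genes Ccl2, Ccl3 and Ccl4. It also held more RNA of immediate early genes, glucocorticoid-responsive genes and hypoxia targets, and less RNA of genes of fibroblasts and meninges. Ccl2, a chemokine that draws monocytes, rose from 0.0928 ± 0.186 CPM to 4.46 ± 1.03 (log2 fold change 5.59 ± 0.63, edgeR adjusted p = 0.000118). Il1b, the gene of the inflammatory cytokine interleukin-1β, rose from 0.216 ± 0.236 to 4.57 ± 2.16 CPM (log2 fold change 4.37 ± 0.65, edgeR adjusted p = 0.000949). Ccl3 and Ccl4, chemokines of activated myeloid cells, rose by 5.48 ± 0.82 and 6.40 ± 1.16. Of 20 cytokine, chemokine and adhesion genes tested, 6 rose, 2 fell and 12 did not pass, or 7 and 3 passed when adjusted over the list alone (camera adjusted p = 0.00662, and 0.0269 with an estimated correlation). The 2 that fell were Csf1 (-0.53) and Nlrp3 (-1.004), named after their values were seen. Of 27 NF-κB pathway genes, 6 rose and 21 did not pass, or 7 rose when adjusted over the list alone (camera adjusted p = 0.00302, and 0.0146 with an estimated correlation). Rel, an NF-κB subunit, rose by 2.39 ± 0.38, Nfkbia, the inhibitor that NF-κB induces, by 2.13 ± 0.52, and Birc3, an inhibitor of apoptosis, by 1.20 ± 0.27. Libraries 1 and 2 alone gave log2 fold changes of 3.73 for Ccl2, 3.48 for Il1b, 2.24 for Rel and 1.26 for Nfkbia.

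Immediate early genes, transcribed within minutes of neuronal activity or stress, were higher as a group. Of 25 tested, 11 rose, 2 fell and 12 did not pass, or 16 and 2 when adjusted over the list alone (camera adjusted p = 3.27e-06, and 0.0146 with an estimated correlation). Nr4a3, an orphan nuclear receptor, rose from 6.33 ± 5.12 to 73.6 ± 18.8 CPM (log2 fold change 3.54 ± 0.66), the AP-1 subunit Fosl2 rose by 3.14 ± 0.61 and the small Maf factor Maff by 2.45 ± 0.45. The 2 that fell were Cyr61, a secreted matrix protein (-2.55 ± 0.46), and Btg2 (-1.11), the latter named after its value was seen. Glucocorticoid-responsive genes were also higher as a group. Of 18 tested, 11 rose and 7 did not pass, or 14 rose when adjusted over the list alone, and the median log2 fold change was 1.15 (camera adjusted p = 9.86e-10, and 0.00801 with an estimated correlation). Pdk4, a kinase that holds back pyruvate dehydrogenase, rose by 2.64 ± 0.47, Cdkn1a, the cell-cycle inhibitor p21, by 2.40 ± 0.44, the kinase Map3k6 by 2.37 ± 0.52, and Errfi1, a feedback inhibitor of the EGF receptor, by 1.94 ± 0.32. Of 17 circadian clock genes, 4 rose and 13 did not pass (camera adjusted p = 0.0244, but 0.0524 with an estimated correlation and 0.0695 without NC library 1), among them Per2 by 1.09 ± 0.18 and Nfil3 by 1.65 ± 0.43. With libraries 1 and 2 alone the median log2 fold change was 0.74 for the immediate early genes, against 0.77 in all libraries, and 1.14 for the glucocorticoid-responsive genes.

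Targets of hypoxia-inducible factor rose in 10 of 27 cases, 1 fell and 16 did not pass, or 11 and 1 when adjusted over the list alone (camera adjusted p = 0.000286, and 0.00801 with an estimated correlation). The vasodilator peptide gene Adm rose from 2.49 ± 0.824 to 13.5 ± 5.39 CPM (log2 fold change 2.44 ± 0.39). Slc2a1, the glucose transporter of the blood-brain barrier, rose by 0.83 ± 0.17, the angiogenic factor Vegfa by 0.70 ± 0.15 and the mitophagy gene Bnip3 by 0.47 ± 0.11. The 1 that fell was Ak4 (-1.28), named after its value was seen. Hmox1, the inducible heme oxygenase, which itself releases CO from heme, rose from 8.43 ± 1.67 to 13.8 ± 2.24 CPM (log2 fold change 0.71 ± 0.16), within a list of 21 heme, iron and NRF2 genes of which 18 did not pass (camera adjusted p = 0.347). Of 17 heat shock genes, 6 rose and 11 did not pass (camera adjusted p = 0.000361, and 0.0313 with an estimated correlation). The co-chaperones Bag3 and Dnajb1 rose by 1.04 ± 0.19 and 0.64 ± 0.15. Hspa1b rose by 3.65 ± 0.71, a value that is uncertain because a near-identical gene can take its reads. Of 18 unfolded-protein and integrated stress response genes, 4 rose and 14 did not pass, or 8 rose when adjusted over the list alone, with Hspa5, the chaperone BiP, at 0.61 ± 0.10 (camera adjusted p = 0.0034, but 0.0588 with an estimated correlation). The log2 fold changes in libraries 1 and 2 alone were 1.92 for Adm, 0.76 for Slc2a1, 0.69 for Hmox1, 1.01 for Bag3 and 0.53 for Hspa5.

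Markers of cell types and brain regions moved too. The labels give neither the part of the brain sampled nor the time after exposure, so these values cannot tell a change in expression from a difference in the tissue taken. Of 16 fibroblast and meningeal genes, 6 fell and 10 did not pass, or 7 fell when adjusted over the list alone (camera adjusted p = 1.36e-05, and 0.00801 with an estimated correlation). The collagen gene Col1a2 fell from 86.5 ± 27.9 to 12.9 ± 11.5 CPM (log2 fold change -2.74 ± 0.64) and the proteoglycan gene Dcn from 36.3 ± 6.54 to 15.3 ± 4.43 (-1.24 ± 0.18). Of 14 pericyte and smooth muscle genes, 4 fell, among them Vtn (-1.53 ± 0.27), and of 12 genes of ependyma and motile cilia, 2 fell, Spag17 (-2.89 ± 0.43) and Pifo (-1.55 ± 0.35). Their camera adjusted p-values, 0.000636 and 0.000805, became 0.0588 and 0.0588 with an estimated correlation. Of 17 astrocyte genes, the folate enzyme gene Aldh1l1 fell (-0.77 ± 0.20) and 16 did not pass (camera adjusted p = 0.00572, and 0.0524 with an estimated correlation). Of 16 pan-neuronal genes, 5 rose and 11 did not pass (camera adjusted p = 0.0025, and 0.0146 with an estimated correlation), including the synaptic genes Snap25 (0.48 ± 0.09) and Syn1 (0.62 ± 0.14). Of 14 cortical genes, 3 rose and 11 did not pass (camera adjusted p = 0.00554, and 0.0524 with an estimated correlation). The transporter and enzyme genes of dopamine and serotonin neurons Slc6a3, Tph2 and Ddc, whose cells lie in the brainstem, fell by 8.59, 3.93 and 2.72 (3 of 6 listed genes, camera adjusted p = 0.000937, and 0.11 with an estimated correlation). Slc6a3 differed widely inside the untreated group, with 47.8 CPM in NC library 1 and 0.648 in library 2. The hypothalamic peptide genes Oxt and Avp rose by 8.37 ± 1.24 and 6.90 ± 1.36, but both stood at 126 CPM in CO library 1, and Oxt at 0 and Avp at 0.387 CPM in library 2. NC library 2 also stood below NC library 1 for Tph2 (5.93 against 69.6 CPM) and Ddc (8.20 against 43.8 CPM). Median log2 fold changes in libraries 1 and 2 alone were -0.90 for fibroblast, -0.74 for pericyte, -0.96 for ependymal, -0.31 for astrocyte and -2.40 for monoamine neuron genes. In all libraries they were -0.70, -0.66, -1.09, -0.27 and -2.27.

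Genes of efferocytosis, the process in the series title, did not move together. Of 33 tested, 2 rose, 2 fell and 29 did not pass (camera adjusted p = 0.892). Mertk, a receptor by which phagocytes bind dying cells, rose from 28.8 ± 7.40 to 43.8 ± 11.7 CPM (log2 fold change 0.60 ± 0.19, edgeR adjusted p = 0.0446). Its call was lost (edgeR adjusted p 0.0511 to 0.0993) without any 1 of NC libraries 1, 3, 4, 5 or 6 or CO libraries 2, 3, 4 or 6. Ucp2, a mitochondrial carrier that sustains engulfment, fell by 0.57. Of 19 microglial genes, the complement gene C1qa rose by 0.60 ± 0.16 and the purinergic receptor gene P2ry12 fell by 0.90, while 17 did not pass (camera adjusted p = 0.699).

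Over all genes tested between CO and NC, 2110 of 16581 changed, 1048 higher and 1062 lower in CO. Some of the largest changes were in single genes whose reads can be shared with near-identical copies and are therefore uncertain: Amy2a3 was at least 1710-fold and RT1-CE16 at least 456-fold higher in CO, with NC at 0, and Hbb at least 3130-fold lower, with CO at 0. Library 1 weighed on 2 of these bounds. Amy2a3 had 137 CPM in CO library 1 and 2.90 in library 2, with a bound of 1030-fold without library 1, and Hbb had 316 CPM in NC library 1 and 0.093 in library 2, with a bound of 2000-fold without library 1. These bounds set 3 counts over the group at 0 and, like all counting intervals here, cover counting error only. Impad1, a phosphatase gene, fell from 7.28 ± 2.67 to 0.291 ± 0.230 CPM. Of the 42 lists, 18 passed camera, 12 higher and 6 lower, and 8 also passed with an estimated correlation: NF-κB, cytokines, pan-neuronal, fibroblasts, hypoxia, immediate early, heat shock and glucocorticoid. Libraries 1 and 2 alone gave 4 genes by edgeR, 51 by DESeq2, and 594 of 16820 at an unadjusted p under 0.05, fewer than the 841 that chance gives. The other splits of those 4 libraries gave 387 and 519 at that limit. The 4, RT1-CE16, Fam131a, Nr4a3 and Fosb, the last named only because it passed there, were all higher in CO. With an estimated correlation no list passed in those libraries after adjustment, while 8 did at an unadjusted p under 0.05, where chance gives 2.1, and 23 with the preset correlation.

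**Figure D3:**
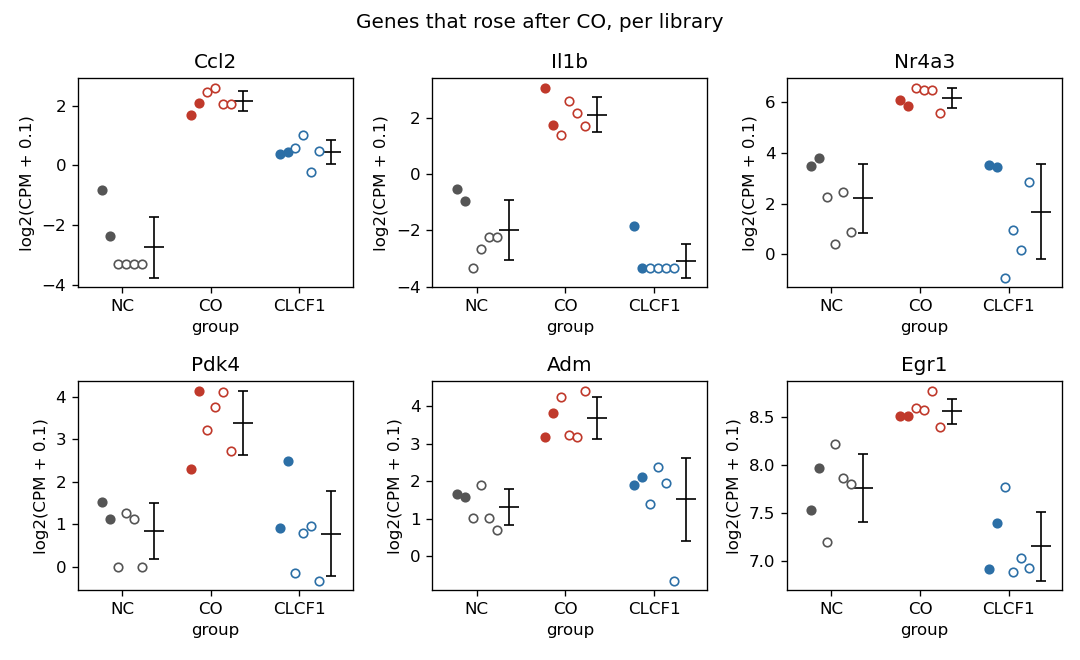
Levels of 6 genes in each library as log2(CPM + 0.1), with filled points for libraries 1 and 2, open points for libraries 3 to 6, and bars for the mean and SD of 6 libraries per group. Ccl2, Il1b, Nr4a3, Pdk4, Adm and Egr1 were all higher in CO than in NC, by 5.59, 4.37, 3.54, 2.64, 2.44 and 0.77 in fitted log2 fold change.

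The second comparison, CLCF1 against CO, asks what the knock-down label changed among CO-exposed rats. The CLCF1 group held less RNA of immediate early genes, hypoxia targets and clock genes than CO, and more RNA of fibroblast genes. Choroid plexus genes were also higher and cytokine genes lower as lists, but both lost the camera call with an estimated correlation (adjusted p = 0.0506 and 0.092). As said above, the labels give neither the part of the brain sampled nor the time after exposure. In all 3 comparisons, differences in clock or cell-type genes can therefore not be told from differences in time of sampling or tissue taken. Il1b was 171-fold lower by the ratio of its counts (95% counting interval 58.2 to 833), with 3 counts in the CLCF1 group against 440 in CO. The neutrophil-attracting chemokine gene Cxcl2 was at least 49-fold lower, with no count in any CLCF1 library, and Ccl3 fell by 5.40. Ccl2 fell from 4.46 ± 1.03 to 1.31 ± 0.385 CPM (log2 fold change -1.76 ± 0.47, edgeR adjusted p = 0.0164). Of 20 cytokine, chemokine and adhesion genes, 6 fell, 2 rose and 12 did not pass, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.0415, but 0.092 with an estimated correlation). The list's call was also lost (camera adjusted p 0.0507 to 0.0695) without any 1 of CO libraries 2, 4 or 6 or CLCF1 libraries 1, 2 or 5. The 2 that rose were Ccl7 (2.43) and Nlrp3 (1.03), named after their values were seen. Of 27 NF-κB genes, 6 fell and 21 did not pass, or 7 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0605). Nfkb1, the p50 precursor, fell by 0.84, Rel by 1.39, Ikbkg, the regulatory part of the IκB kinase, by 1.67, and the NF-κB cofactor gene Nfkbiz by 2.24. Socs3 fell by 2.99. The corresponding values of libraries 1 and 2 alone were -1.58 for Ccl2, -4.27 for Ccl3, -0.59 for Nfkb1, -1.23 for Rel and -2.39 for Socs3.

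Immediate early genes were lower in CLCF1 than in CO as a group. Of 25 tested, 20 fell and 5 did not pass, or 22 fell when adjusted over the list alone, with a median log2 fold change of -1.60 (camera adjusted p = 6.57e-22, and 6.73e-05 with an estimated correlation). Egr2, a zinc finger factor, fell from 23.6 ± 6.41 to 2.66 ± 0.915 CPM (log2 fold change -3.14 ± 0.30, edgeR adjusted p = 1.88e-05). Egr1 fell from 379 ± 34.1 to 146 ± 40.1 CPM (-1.38 ± 0.17), the MAP kinase phosphatase gene Dusp1 by 2.10 and the nuclear receptor gene Nr4a1 by 2.54. In libraries 1 and 2 alone the list's median was -1.58, and p with an estimated correlation was 0.00178 before adjustment. Of 18 glucocorticoid-responsive genes, 6 fell, 2 rose and 10 did not pass, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.000648, but 0.0574 with an estimated correlation). Pdk4 fell by 2.48, Errfi1 by 2.12 and Tsc22d3, the glucocorticoid-induced leucine zipper, by 1.59, whereas Lcn2, the iron-binding protein lipocalin-2, rose by 1.73 ± 0.46. The second gene that rose was Sult1a1 (0.67), named after its value was seen. Of 17 clock genes, 7 fell and 10 did not pass (camera adjusted p = 0.00675, and 0.0438 with an estimated correlation), with Per1 at -1.89 ± 0.46, Per2 at -1.05 ± 0.18 and Nfil3 at -2.20 ± 0.44.

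Of 27 hypoxia targets, 8 fell and 19 did not pass, or 10 fell when adjusted over the list alone (camera adjusted p = 0.00153, and 0.0364 with an estimated correlation). Slc2a1 fell from 211 ± 51.3 to 97.1 ± 12.7 CPM (log2 fold change -1.12 ± 0.17), Adm by 2.03, the stress gene Ndrg1 by 1.21 and Vegfa by 0.78, and Hmox1 fell by 0.60. Of 17 heat shock genes, 6 fell (camera adjusted p = 0.000648, but 0.0506 with an estimated correlation), among them Dnajb1 (-1.28 ± 0.15) and Bag3 (-1.04 ± 0.19). Of 18 unfolded-protein and integrated stress response genes, 7 fell (camera adjusted p = 0.00768, but 0.092 with an estimated correlation), with Hspa5 at -0.52 ± 0.10, Chac1, a glutathione-degrading enzyme gene, at -0.82 ± 0.18 and Creld2 at -0.60 ± 0.15. In libraries 1 and 2 alone Slc2a1, Adm, Dnajb1 and Hspa5 had log2 fold changes of -1.08, -1.55, -0.90 and -0.39.

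Among cell-type genes the choroid plexus, the epithelium that makes cerebrospinal fluid, had the largest difference. Of its 13 genes tested, 11 rose in CLCF1 and 2 did not pass, or 13 rose when adjusted over the list alone, with a median log2 fold change of 4.17 (camera adjusted p = 6.28e-10, but 0.0506 with an estimated correlation). Ttr, the thyroid hormone carrier transthyretin, averaged 2681 ± 2101 CPM in CLCF1 against 9.52 ± 12.3 in CO, and it stood at 5703 CPM in CLCF1 library 1 and 5.40 in library 2. Kl, the aging-related gene klotho, rose by 6.58 ± 0.94 and the coagulation factor gene F5 by 6.37 ± 0.82. Kl stood at 43.6 CPM in CLCF1 library 1 and 1.12 in library 2. The sodium bicarbonate carrier gene Slc4a5 was at least 254-fold higher, with no count in any CO library, 306 counts in CLCF1 library 1 and 1 in library 2. Of 16 fibroblast and meningeal genes, 4 rose and 12 did not pass, or 9 rose when adjusted over the list alone, with Dcn at 1.10 ± 0.18 (camera adjusted p = 0.0004, and 0.0399 with an estimated correlation). Of 12 ependymal genes, 4 rose, including Pifo (1.84 ± 0.35; camera adjusted p = 0.0212, but 0.189 with an estimated correlation). Of 21 myelin genes, 6 fell and 15 did not pass, or 11 fell when adjusted over the list alone (camera adjusted p = 3.85e-05, but 0.189 with an estimated correlation), with Mag, the myelin-associated glycoprotein, at -0.999 ± 0.19 and the lipid enzyme gene Fa2h at -1.09 ± 0.27. Median log2 fold changes of libraries 1 and 2 alone were 4.53 for choroid plexus, 0.76 for fibroblast, 0.75 for ependymal and -0.49 for myelin genes. Other lists also passed camera and lost the call with an estimated correlation: 13 excitatory neuron genes, of which 2 fell (camera adjusted p = 0.0391, and 0.092 with an estimated correlation), and 13 striatal genes, of which 2 fell (camera adjusted p = 0.00149, and 0.197 with an estimated correlation). The excitatory neuron call was also lost (camera adjusted p 0.0501 to 0.0695) without any 1 of CO libraries 2 or 4 or CLCF1 libraries 5 or 6.

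The interferon, antigen presentation and lymphocyte lists passed camera as higher in CLCF1 than in CO, but all 3 lost the call with an estimated correlation. Of 27 interferon-responsive genes, 9 rose and 18 did not pass, or 14 rose when adjusted over the list alone (camera adjusted p = 0.000755, but 0.092 with an estimated correlation). The interferon-induced GTPase genes Ifi47, Gbp5 and Igtp rose by 1.92 ± 0.42, 1.79 ± 0.42 and 0.79 ± 0.19. Of 19 antigen presentation genes, 6 rose, 2 fell and 11 did not pass, or 8 and 2 when adjusted over the list alone (camera adjusted p = 0.026, but 0.135 with an estimated correlation, 0.0738 without CO library 2 and 0.0667 without CLCF1 library 1). The members that moved most were class I and class II genes of the RT1 locus, which share reads and are uncertain: RT1-CE5 was 73.1-fold lower by the ratio of its counts (24.6 to 358) and RT1-Bb rose by 1.95 ± 0.49. Of 6 lymphocyte genes, the T cell co-receptor gene Cd8a rose from 0.0510 ± 0.0701 to 2.53 ± 0.639 CPM and the immunoglobulin gene Ighm from 0.253 ± 0.269 to 2.75 ± 2.57 (camera adjusted p = 0.0415, but 0.092 with an estimated correlation). The call was also lost (camera adjusted p 0.0526 to 0.0818) without any 1 of CO libraries 2, 3 or 4 or CLCF1 library 1. That list's median was -0.004 and its mean and test were positive. Microglial genes (2 of 19 rose, camera adjusted p = 0.0888), border macrophage genes (3 of 14 rose, 0.0821) and complement genes (4 of 20 rose, 0.0636) did not pass as lists. Their called members included Gpr34 and Ly86, 2 microglial surface genes, at 0.97 ± 0.25 and 1.15 ± 0.30, the phagocyte oxidase gene Cybb at 1.36 ± 0.33 and the complement protease gene C1s at 1.05 ± 0.20. The efferocytosis list again did not pass, with 2 of 33 genes higher, 3 lower and 28 not passed (camera adjusted p = 0.968, median -0.008 against a test direction of higher). Gulp1, an adaptor of engulfment receptors, rose from 9.88 ± 2.00 to 20.9 ± 2.90 CPM (log2 fold change 1.08 ± 0.19), and Pparg, a nuclear receptor of lipid-laden macrophages, fell by 1.62.

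Over all genes tested between CLCF1 and CO, 2814 of 16581 changed, 1431 higher and 1383 lower in CLCF1. Of the 42 lists, 16 passed camera, 6 higher and 10 lower, and 4 of them also with an estimated correlation: fibroblasts, hypoxia, immediate early and clock. Libraries 1 and 2 alone gave 8 genes by edgeR, 99 by DESeq2 and 817 of 16820 at an unadjusted p under 0.05, where chance gives 841. The other splits of those 4 libraries gave 524 and 1888, the latter above the real one. Of the 8, Aqp1 and LOC100911372 were higher in CLCF1, and Fosb, Fam131a, Nr4a3, Egr2, Fos and Errfi1 were lower, some of them named only because they passed there. No list passed there after adjustment with an estimated correlation, while 7 did at an unadjusted p under 0.05, where chance gives 2.1, and 23 with the preset correlation.

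The third comparison, CLCF1 against NC, asks how far CO-exposed rats with the knock-down label stood from untreated ones. The CLCF1 group had less RNA of immediate early genes than NC and more RNA of Ccl2. Choroid plexus genes, higher, and monoamine neuron genes, lower, passed camera but lost the call with an estimated correlation (adjusted p = 0.219 and 0.235). Both lists varied widely between libraries 1 and 2, with Ttr at 5.40 CPM in CLCF1 library 2 against 5703 in library 1 and Tph2 at 5.93 CPM in NC library 2 against 69.6 in library 1. Of 25 immediate early genes, 8 fell, 1 rose and 16 did not pass, or 11 and 1 when adjusted over the list alone (camera adjusted p = 5.28e-08, and 0.0168 with an estimated correlation, the only list of this comparison to hold). Egr2 fell from 21.6 ± 8.24 to 2.66 ± 0.915 CPM (log2 fold change -3.02 ± 0.30, edgeR adjusted p = 2.25e-05), Cyr61 by 3.64, Dusp1 by 1.66 and the neuronal activity factor gene Npas4 by 1.74. The 1 that rose was Fosl1 (1.07), named after its value was seen. The list's median was -0.80 in all libraries and in libraries 1 and 2 alone. Ccl2 rose from 0.0928 ± 0.186 to 1.31 ± 0.385 CPM (log2 fold change 3.83 ± 0.63), whereas Cxcl2 was at least 13.8-fold lower, and 18 of 20 cytokine genes did not pass (camera adjusted p = 0.714). Of 13 choroid plexus genes, 9 rose and 4 did not pass, or 11 rose when adjusted over the list alone (camera adjusted p = 1.15e-08, but 0.219 with an estimated correlation), among them Kl by 6.32 ± 0.91 and F5 by 5.91 ± 0.79. Of 6 monoamine neuron genes, 4 fell, including Tph2 by 3.46 and Ddc by 3.32, and 2 did not pass (camera adjusted p = 0.00232, but 0.235 with an estimated correlation). Of these 2, Th, named here after its values were seen, was higher on average in CLCF1. It held 49, 785, 243, 725, 449 and 659 counts in the CLCF1 libraries, and 693, 31, 256, 248, 99 and 103 in NC. The medians of these lists were 4.44 and -2.44 in all libraries, and 3.23 and -1.82 in libraries 1 and 2 alone.

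Of 21 myelin genes, 2 fell, or 7 when adjusted over the list alone (camera adjusted p = 0.000167, but 0.353 with an estimated correlation), and of 17 astrocyte genes, 3 fell, including Aldh1l1 (-1.21 ± 0.20; camera adjusted p = 0.0466, but 0.225 with an estimated correlation). The astrocyte call was also lost (camera adjusted p 0.0619 to 0.0724) without any 1 of NC library 1 or CLCF1 libraries 1, 3 or 5. Of 33 efferocytosis genes, 3 fell, 1 rose and 29 did not pass (camera adjusted p = 0.98), with Pparg at -2.28 ± 0.36 and the phosphatidylserine receptor gene Stab2 at -3.59 ± 0.68. NF-κB genes did not pass as a list (1 of 27 rose, 2 fell, camera adjusted p = 0.426). Of 17 reactive astrocyte genes, 3 rose, among them Lcn2 (2.88 ± 0.49) and the sphingosine receptor gene S1pr3 (2.91 ± 0.62), and the list did not pass (camera adjusted p = 0.0609). RT1-CE16 was at least 947-fold and RT1-Ba at least 176-fold higher in CLCF1, with NC at 0, and RT1-CE5 was 156-fold lower by the ratio of its counts (53.2 to 762), all 3 uncertain as above. Over all genes tested, 1536 changed, 734 higher and 802 lower. Of the 42 lists, 5 passed camera. Libraries 1 and 2 alone gave 2 genes by edgeR, RT1-CE16 and, named only because it passed there, LOC100911372, 51 by DESeq2, and 418 of 16820 at an unadjusted p under 0.05, fewer than the 841 that chance gives. Both other splits of those 4 libraries gave more, 677 and 1438. With an estimated correlation no list passed in those libraries after adjustment. Only 1 did at an unadjusted p under 0.05, where chance gives 2.1, and 10 passed with the preset correlation.

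**Figure D4:**
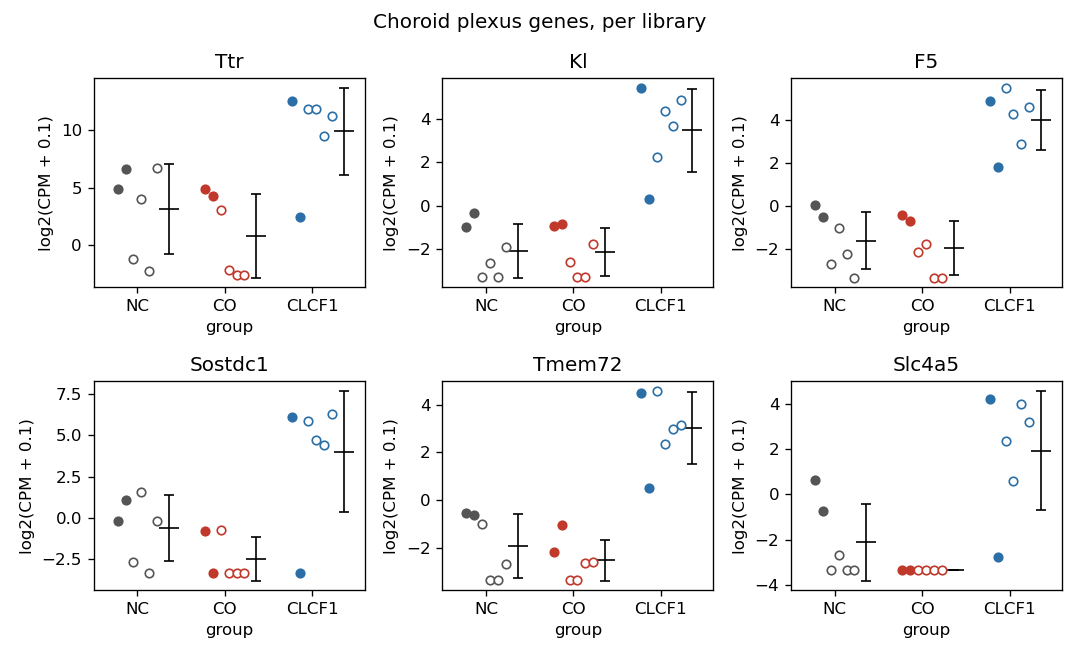
Levels of 6 choroid plexus genes in each library as log2(CPM + 0.1), with filled points for libraries 1 and 2, open points for libraries 3 to 6, and bars for the mean and SD of 6 libraries per group. In the CLCF1 group Ttr stood at 5703 CPM in library 1 and at 5.40 in library 2, and it averaged 2681 CPM.

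The last comparison set the change after CO against the change between CLCF1 and CO, which asks whether the CLCF1 group lay nearer to NC than CO did. Of 953 genes called in both, 934 had opposite signs and 19 the same sign. There were 365 genes higher in CO than NC and lower in CLCF1 than CO, against 87.4 in independent lists of these sizes, and 569 with the opposite course, against 91.7. Independent lists leave out the shared CO libraries, so these are not the numbers that no change would give, and groups simulated without any change gave 0 such genes in each of 5 draws. Examples, picked after their values were seen, are Ccl2, Il1b, Nr4a1, Egr1, Pdk4, Errfi1, Adm, Slc2a1, Hmox1, Bag3 and Hspa5 for the former and Dcn, Tyk2 and Vtn for the latter. Both contrasts contain the CO libraries with opposite sign, which by itself gives a negative correlation. Across the 16581 genes, which are not independent replicates, r of the log2 fold changes was -0.546, and groups simulated without any change gave -0.504 on average (100 draws, -0.527 to -0.478). The covariance was -0.306 against a simulated -0.0497, a difference of -0.256. All simulated draws, those counting opposite-sign genes included, took the libraries as independent samples, which the genes without counts argue against for libraries 3 to 6. The error that both contrasts share may therefore exceed the simulated one. The simulated values thus do not bound what no change would give. With the CO libraries split between the contrasts, r was -0.413 on average (20 splits, -0.456 to -0.385) and the covariance -0.252. Such a split removes the shared error only if the CO libraries are independent, which the genes without counts argue against for libraries 3 to 6. In libraries 1 and 2 alone r was -0.531, and with 1 CO library for each contrast it was between -0.0889 and -0.0572. Of the 1048 genes higher in CO than NC, 779 were not called between CLCF1 and NC, and of the 1062 lower, 923 were not. Over all 16581 genes tested, only 9.26% were called between CLCF1 and NC, so most genes of any kind were not called there. These 2 counts therefore do not show a return to NC.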

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

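The tests of sample-like variation, of repeat sequencing, of choroid plexus tissue in single libraries, of RT1 haplotypes, of antigen presentation with 1 model of Tap2 and of other splits of the libraries were chosen only after the result was seen.

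Genes that belong together varied together between libraries 1 and 2, with median variance ratios of lists of 1.14 to 1.78, while that median was at most 0.846 in pairs among libraries 3 to 6, where 4 of 39 lists still lay above the 95th percentile of random lists. Variation between samples like that of libraries 1 and 2 is argued against for libraries 3 to 6 by genes without counts, since of those at 0 in a pair of libraries 3 to 6 at least 1.24% were above 0 in library 1 or 2, and none was in the other direction. Repeat sequencing of 1 RNA is argued against by a chi-square per degree of freedom of at least 52.4 in every pair among libraries 3 to 6. A test written before its result was seen asked whether each gene's value in libraries 3 to 6 may have been set separately from other genes, around its level in libraries 1 and 2; of genes at 0 in libraries 1 and 2, 0.0% were above 0 in libraries 3 to 6, as that hypothesis needs. How such values would arise was not tested and stays open, no biological explanation was tested, and p-values that rest on libraries 3 to 6 then measure a spread of unknown origin.

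Choroid plexus genes were higher in the CLCF1 group than in CO and NC. Tissue of the choroid plexus in CLCF1 library 1 is a candidate explanation for that library, since 11 of the 13 listed genes were higher there than in library 2 by a log2 difference of 1 or more (median difference 4.63). Unequal amounts of tissue among CLCF1 libraries 3 to 6 stay open, since few lists varied together there, so a variance ratio of the list's mean of 0.951, against 9.55 between libraries 1 and 2, decides nothing. Higher expression of the list in every brain of the group also remains open, since both CLCF1 libraries 1 and 2 lay above those of the other groups in 6 of the 13 genes, between the bounds set beforehand. It did not hold for Ttr, with only 111 counts in CLCF1 library 2. Ttr had 432 and 2076 counts in NC libraries 1 and 2, and 492 and 295 in those of CO. In library 2 Ttr and Sostdc1 lay far below the other CLCF1 libraries, with gaps of 0.698 and 0.804 of the range.

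Several genes of the RT1 locus, the rat major histocompatibility complex, were near 0 in 1 group and expressed in another. Of 24 tested, 6 were higher and 7 lower in CLCF1 than in NC, and of these 2 groups 4 were expressed in CLCF1 and near 0 in NC and 2 the other way, while CO libraries 1 and 2 expressed genes of both kinds (RT1-CE16 at 13.4 and RT1-CE5 at 2.93 CPM). Class I genes went both ways, whereas the class II genes called, RT1-Ba, RT1-Bb, RT1-Da and RT1-DOb, were all higher in CLCF1. RT1-Db1, RT1-DMa and RT1-DMb, also of class II, did not pass. A change of antigen presentation as a whole is argued against by a median log2 fold change of 0.242 over 9 gene models of 8 pathway genes outside the variable RT1 models (0.196 or 0.344 with only 1 of the 2 models of Tap2; Ciita had too few counts), although Cd74 (1.12) and Tapbp (0.86) rose. The class II genes were not tested as a set, so that median leaves a change of them alone open. Animals of different RT1 haplotypes in the groups may explain the RT1 pattern and cannot be told apart from reads shared between RT1 genes, because the haplotypes are not known and such a difference would follow the groups. Of 133 genes tested in the region (chromosome 20, positions 154074 to 5421098 as the table gives them) 17.3% were called, against 9.19% elsewhere and 9.17% of the 109 genes there other than RT1.

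Chance cannot be judged for the counts of changed genes by splits of all libraries. In each comparison 1 of 100 splits of the 12 libraries, the real one, gave as many genes as the real one, with 2110, 2814 and 1536 for CO against NC, CLCF1 against CO and CLCF1 against NC and at most 11, 15 and 64 in the others. The real split would also come first if libraries 3 to 6 had been set around libraries 1 and 2 of their group, so this decides nothing. Only 3 splits are possible with libraries 1 and 2 alone, too few for a share under 0.05. There the real split gave 594, 817 and 418 genes at an unadjusted p under 0.05, and the highest other split 519, 1888 and 1438.

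A single library lay far from the other 5 of its group in 32 of 345 groups of values (9.3%), where chance gives about 1 in 20. Of these, 15 were library 1 or 2 and 17 were libraries 3 to 6. The numbers below are the gap to the nearest other library divided by the group's range. The number of genes at 0 in CO library 2, 15876, gave 0.764. That number had a range of only 38 among CO libraries 3 to 6, against 243 between CO libraries 1 and 2. In NC the range was 15 among libraries 3 to 6 and 1014 between libraries 1 and 2, and in CLCF1 it was 52 and 554. The ratio therefore does not show whether CO library 2 or the closeness of libraries 3 to 6 is unusual. Genes of monoamine and peptide neurons stood apart mostly in library 2, with Slc6a3 at 0.781 in NC and 0.674 in CO, Tph2 at 0.67 and Ddc at 0.798 in NC, and Oxt at 0.839 and Avp at 0.729 in CO. In CO library 4 Tph2 gave 0.645. Il1b in CLCF1 had counts in library 1 and in no other (1.0). Amy2a3 in CLCF1 library 1 gave 0.817 and Impad1 in NC library 6 gave 0.66. Among CO libraries, library 1 stood apart for Ucp2 (0.695), Pifo (0.73) and Bnip3 (0.767), library 2 for Fosl2 (0.723), library 3 for Tyk2 (0.699), Per2 (0.634) and Fezf2 (0.718), and library 5 for Bag3 (0.643). Among NC libraries, library 3 stood apart for Hmox1 (0.68), library 4 for Tsc22d3 (0.648), and library 5 for Birc3 (0.761) and Maff (0.66). Among CLCF1 libraries, library 4 stood apart for Egr2 (0.791) and Per1 (0.628), library 5 for Hmox1 (0.702), Cyr61 (0.653) and Btg2 (0.79), and library 6 for Adm (0.678) and Dusp1 (0.642).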

How the results depend on the processing

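Only the fits on libraries 1 and 2 alone and on libraries 3 to 6 alone were chosen after the result was seen. In what follows counts are given for CO against NC, CLCF1 against CO and CLCF1 against NC, in that order, and where a cause is not named the cause was not tested.

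The counts of changed genes (2110, 2814 and 1536) stayed within 1.5 times with the scalings, limma-voom, the stricter filter and fits of only the 2 groups. They rose to 4291, 5645 and 4292 without a filter, which still called 2108, 2812 and 1536 of the original genes, and to 4170, 5254 and 3844 with DESeq2, which called 2103, 2811 and 1534 of them. An added fold change limit left 1088, 1468 and 913 by construction. Libraries 1 and 2 alone gave 4, 8 and 2, and libraries 3 to 6 alone gave 918, 1436 and 736, both with fewer samples. Leaving out 1 library gave 1672 to 2137, 2427 to 3033 and 1219 to 1692 genes.

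The counts of changed lists (18, 16 and 5) fell to 8, 4 and 1 with an estimated correlation, and fry, which does not compare a list with other genes, gave 23, 30 and 19. In CLCF1 against NC the stricter filter gave 9 and libraries 1 and 2 alone gave 11, of which 10 were among the 42 lists tested in all libraries. Leaving out 1 library gave 14 to 20, 13 to 20 and 5 to 10, the last with 10 without NC library 2, 9 without NC library 4, 8 without NC library 6 and 9 without CLCF1 library 4. Of the lists that passed, 14, 12 and 4 passed without any 1 library.

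The library number as a block gave 1944, 2787 and 1477 genes, of which 1707, 2465 and 1265 were among the original ones, and 18, 19 and 4 lists. Only 1 of 18 same-number pairs had a correlation of deviations above 0.1 (range -0.0283 to 0.149), and 5 correlated best with their own number. Those 5 were libraries 1, 2 and 3 between NC and CO and libraries 1 and 2 between CO and CLCF1. All same-number correlations of libraries 1 and 2 were positive, from 0.0043 to 0.149. Values set separately per gene in libraries 3 to 6 could show no pairing. A weak pairing of libraries 1 and 2 by number therefore stays open. The reversal's r of -0.546 became -0.413 with the CO libraries divided between contrasts, which removes their shared error only if those libraries are independent, and lay from -0.561 to -0.514 with 1 CO library left out. Clcf1 had log2 fold changes of 4.58 and -6.05 in libraries 1 and 2 alone, where neither passed. Whether the smaller number of samples ended these calls was not tested.

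Of the genes named by the rule, those that turned in sign had not passed. Lifr in CLCF1 against CO went from -0.05 to 0.14 with the block, 0.23 with limma-voom, 0.46 in libraries 1 and 2 alone, and -0.35 to 0.70 with 1 library left out. Cd3e in the same comparison lay from -0.80 to 0.024, the latter without CO library 1. Cntfr in CLCF1 against NC stood near 0, at -0.007 with DESeq2 size factors, -0.014 with library size alone, -0.001 without a filter, -0.005 with the stricter filter, -0.007 with DESeq2, -0.014 with only the 2 groups, -0.053 in libraries 3 to 6 alone, and -0.096 to 0.113 with 1 library left out. Of 491 values of named genes, libraries 1 and 2 alone kept 153 on their side of the threshold and ended 337 calls, and leaving out 1 library kept 5317 of 5904 values. Depth limits genes with few counts, of which the fold changes are bounds or ratios of counts.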

Other observations

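Only the values of libraries 1 and 2 alone, and which lists to describe here, were chosen after the result was seen.

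Cortical and excitatory neuron genes included several that were higher after CO. Of 13 excitatory neuron genes tested between CO and NC, 4 rose and 9 did not pass (camera adjusted p = 0.0355, and 0.0588 with an estimated correlation). Among them Slc17a7, the vesicular glutamate transporter of cortical cells, rose by 0.54 ± 0.13 (log2 fold change ± standard error), Fezf2, a factor of deep cortical layers, by 0.98 ± 0.27, and Nrgn, a postsynaptic calmodulin-binding protein, by 0.71 ± 0.19. The list's call was lost without NC library 1 (camera adjusted p = 0.0988), CO library 2 (0.0561) or CO library 4 (0.0573), and that of Nrgn without NC library 3 (edgeR adjusted p = 0.0559). Of 13 striatal genes, 1 rose and 12 did not pass, with a median log2 fold change of 0.83 (camera adjusted p = 0.0246, but 0.395 with an estimated correlation and 0.187 without NC library 1). Of 15 inhibitory neuron genes, all 15 did not pass between CO and NC (camera adjusted p = 0.872).

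Of 13 proteins encoded by the mitochondrial genome, 1 fell after CO and 12 did not pass, with a median log2 fold change of -0.21 (camera adjusted p = 0.0355, but 0.385 with an estimated correlation). Their call was lost (camera adjusted p 0.0533 to 0.146) without any 1 of NC libraries 1 or 5 or CO libraries 1, 3 or 4. Nuclear genes of cytochrome c oxidase, which CO inhibits, and of the respiratory chain did not pass as a list in any comparison (30 genes, camera adjusted p = 0.2, 0.847 and 0.293), and between CO and NC 2 rose and 28 did not pass. Between CLCF1 and CO, 3 of 15 inhibitory neuron genes rose and 1 fell (camera adjusted p = 0.191).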
